A study of Mus musculus with 3 samples.

How the data were processed

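Pancreatic islets of 2 mice with a beta-cell knockout of IRE1α and of 1 floxed control mouse, all NOD/ShiLtJ and 5 weeks old, were compared. Per the labels' protocols, every mouse had received tamoxifen (10 mg per ml, on 5 days), islets were freed with collagenase, picked by hand, kept overnight in culture and dissociated with accutase, and libraries were made with droplets of the 10X Genomics system. Cell Ranger 3.0.0 and the genome build mm10 are named in the submitters' processing notes. How cells were filtered, how doublets and free RNA were treated, how cells were assigned to types and which test gave the p-values are not given in the sources used here. Cell types are those of the authors' tables. Steps that act before the counts, such as the overnight culture and the dissociation, can alter immediate early and stress genes, and free RNA or doublets can carry abundant hormone transcripts into other cells.

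The authors deposited, per cell type, a table of genes with a signal value per column, which is the mean number of UMIs per cell. This was worked out from the values: in each column, every value times 1 whole number, the cell number, gave whole UMIs within 0.001, for 100% of genes except in control beta cells (99.99%, the exception being a very large value limited by the digits kept). The means were not scaled for depth. The beta-cell table pools the cells of both knockout mice; the alpha and delta tables have 1 column per mouse. The columns of the knockout mice name the group and a number, which was not matched to a particular sample, so they are called the first and the second column. Tables also hold p-values and q-values which the authors computed from cells; cells are not replicates, so these were used only to know which genes were listed and for the rule on named genes, and are quoted as the authors'. The values of q times rank over p in the authors' deposited table give 18527, 16153 and 15393 genes tested in beta, alpha and delta cells, so that 44.2%, 1.15% and 1.50% of them were listed. Genes the tables leave out were not analysed here. A list's measured members are those that the authors listed for that cell type, so its count describes only these. The other members may have been tested and not listed. The alpha-cell table's header is shifted by 1 column, which the values show. The 13 beta-cell gene names that a spreadsheet had turned into dates were restored through their Ensembl identifiers; 8187 of 8193, 185 of 186 and 230 of 231 identifiers were found in GENCODE M21, whose coordinates (same build, mm10) are printed.

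From these values, the ratio of knockout over control and its log2 were computed with no pseudocount; in alpha and delta cells the knockout value is the unweighted mean of 2 mice. Where a group had no UMI (95 genes in control and 8 in knockout beta cells), the ratio is a bound against 3 UMIs over that group's cells. Intervals of a ratio are exact (Clopper-Pearson on the split of the UMIs, 95%), cover counting error only, and are narrower than the true uncertainty. Genes were counted by a fold of at least 1.5 in place of a test, since there was 1 control mouse. There were 30 gene lists fixed before the data were examined; lists with at least 3 measured genes are given by their median log2 fold. In the beta-cell table, the only one with over 2000 rows, the median was placed among 10000 random lists of the same size matched on mean expression in 10 bins, as a percentile that describes these libraries; 29 such percentiles were computed.

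The genes named were chosen by a rule set before the data were examined. It took, per table, the 10 highest and 10 lowest log2 folds among genes whose mean in the higher group reached the table's median and whose adjusted p in the authors' deposited table was under 0.05, leaving out predicted genes. It added 22 genes always named where present and up to 4 examples per list, 2 from each end; not every example is printed. Genes outside this rule are said to be chosen after their values were seen; in the report this holds for S100a9, named because edgeR called only 4 genes, and it holds for most genes under other observations. Genes listed for opposite directions between cell types had been named by the rule, or chosen afterwards, in at least 1 of the 2 cell types.

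Alternatives were a fold of 2, a filter on low values, a pseudocount at the 10th percentile of nonzero means, centring on the median, random lists without matching and leaving out either knockout mouse. Added after seeing the data were 2 scalings to the listed UMI totals, a fold of 1.5 in each knockout mouse, and edgeR's quasi-likelihood test on the recovered UMIs of alpha and delta cells, with log cell number or log listed total as offset. That test has 1 residual degree of freedom, borrows the spread from the 2 knockout mice, and runs on genes the authors had already chosen on the same cells, so its adjusted p-values are too small. It was tested on simulated data with 60 changed genes. At a fold of 4 it recovered 14 of 20 genes in alpha and 20 of 20 in delta cells, at a fold of 2 it recovered 1 and 9, and at 1.5 it recovered 0 in either; 0 unchanged genes were called. The simulated genes were drawn independently, with the cell number as offset and without the authors' selection. The simulation therefore does not give the rate of false calls among the listed genes. The random-list percentile was tested on lists drawn from the 8193 beta-cell genes: with 10 genes shifted by a log2 of 0.5, 95 of 100 lists lay above the central 95% of the random lists. With no shift, 5 of 100 lay above it and 5 below it. The lists were drawn at random, so lists of genes that move together were not tested. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.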

Results

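Single-cell RNA profiles of pancreatic islets were compared between NOD mice given as beta-cell knockouts of the endoplasmic reticulum (ER) stress sensor IRE1α and a floxed control NOD mouse. NOD/ShiLtJ mice develop autoimmune diabetes spontaneously. IRE1α, encoded by Ern1, is an ER membrane kinase and RNase that splices the mRNA of the transcription factor Xbp1 when unfolded proteins build up. Islets came from 2 knockout mice and 1 control mouse, all 5 weeks old, and were profiled in droplets with unique molecular identifiers (UMIs), so that each UMI stands for 1 captured transcript. The series title points to beta cells losing their mature state before immune cells enter the islet, and the comparison asks how each endocrine cell type differed between the genotypes.

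For each cell type, the values analysed were mean UMIs per cell of the genes that the authors' deposited table lists as different, at a largest adjusted p of 0.00998 in beta, 0.0101 in alpha and 0.0103 in delta cells. The beta-cell table gave 8193 genes over 829 control cells and 815 knockout cells, in which the cells of both knockout mice had been pooled. The alpha-cell table gave 186 genes over 142 control cells, with 304 and 177 cells of the knockout mice. In delta cells, 231 genes were given over 101 control cells, with 138 and 78 cells of the knockout mice. Listed genes summed to 31552 UMIs per control beta cell and 24796 per knockout beta cell. Below, a ratio is the UMIs per cell of the knockout over those of the control, and an interval in brackets is the exact 95% interval of that ratio, which covers counting error only. Genes called highest or lowest were ranked among those whose mean in the higher group reached the median of their table. With 1 control mouse no difference had a check against the spread between control mice, and in beta cells none against the spread between knockout mice either.

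The targeted gene did not read lower in the knockout beta cells. Ern1 (ENSMUSG00000020715, mm10 chromosome 11, 106394650 to 106487852) had 0.509 UMIs per control cell and 0.742 per knockout cell, a ratio of 1.46 [1.29 to 1.66]. Xbp1 (ENSMUSG00000020484, chromosome 11, 5520659 to 5525893) had 3.51 and 5.25, a ratio of 1.5 [1.43 to 1.57]. Both lay close to the median of all listed genes, at 1.00 and 1.03 times that median. Which exons were removed and which end of the transcript was read are not given in the sources used here, and reads outside the removed exons check nothing. The label "knockout" is therefore used as the submitters gave it. Neither gene was analysed in alpha or delta cells.

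Beta cells of the knockout mice had lower mRNA of insulin and of several genes of the mature beta cell. Transcripts of progenitor genes and of other islet cells were higher in them, and free RNA or mixed cells were not excluded as the source. Ins2 and Ins1, the mouse insulin genes, went from 13373 to 9146 and from 6900 to 3281 UMIs per cell, ratios of 0.684 [0.683 to 0.685] and 0.475 [0.475 to 0.476]. Iapp, whose product amylin is secreted with insulin, went from 1781 to 935 UMIs per cell. Mafa, a transcription factor of mature beta cells, was at a ratio of 0.364 [0.338 to 0.391]. Ins1 lies on chromosome 19 (52264297 to 52265476) and Ins2 on chromosome 7 (142678656 to 142743381). The insulin genes together made up 64.3% of the listed UMIs in control and 50.1% in knockout beta cells.

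By number, most listed beta-cell genes were higher in the knockout. Of the 8193 genes, 7780 (95.0%) had more UMIs per knockout cell and 413 fewer, and by the size rule of a fold of at least 1.5 there were 3741 higher and 202 lower genes (1314 and 343 after centring on the median). The median log2 fold was 0.54, so gene groups are also given relative to this shift. That split depended on the scaling: 97.2% of genes were higher after scaling to the listed total, 80.5% after scaling to the listed total without Ins1, Ins2 and Iapp, and, by construction, 50.0% after centring on the median. Fold also went with abundance: the median ratio was 3.45 for genes under 0.03 UMIs per control cell and 1.1 for those from 3 to 10, and a rare gene needs a larger fold to be listed.

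Of 12 genes fixed as core beta-cell identity, 7 were measured and 6 were lower, with a median log2 fold of -0.93, or -1.47 relative to all listed genes. This median lay below those of all 10000 random lists matched on expression. Next to the insulins, Iapp and Mafa, the glucose transporter gene Slc2a2 was at a ratio of 0.439 [0.342 to 0.559] and Ucn3, a late maturity marker, at 0.557 [0.484 to 0.641]. Neurod1, shared by islet cell types, was at 1.12 [1.06 to 1.18], which is higher as UMIs per cell and lower relative to the median of all genes. The wider identity list of 22 measured genes split into 12 higher and 10 lower (median 0.09, -0.45 relative to all genes), from Gipr, the receptor of the incretin GIP, at 0.311 [0.226 to 0.422], to the transcription factor gene Rfx6 at 2.03 [1.60 to 2.60]. Among the islet autoantigens of type 1 diabetes, 4 of 6 were lower (median -0.33, which became 0.02 after scaling to the listed total).

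All 10 measured genes of the progenitor and dedifferentiation list were higher, with a median log2 fold of 1.78 that exceeded all 10000 matched random lists. Lists of other cell types, given below, had medians from 0.92 (duct) to 2.10 (acinar) in the same cells. Mixed cells or free RNA were therefore not excluded as a source of progenitor transcripts. Aldh1a3, an enzyme gene used as a marker of dedifferentiated beta cells, went from 0.00965 to 0.0945 UMIs per cell, a ratio of 9.79 [4.73 to 23.5] that rests on few UMIs. Fev, expressed in endocrine progenitors, was at 9.02 [5.79 to 14.7], and Cd81, a surface tetraspanin, went from 0.630 to 4.31 UMIs per cell, a ratio of 6.84 [6.24 to 7.51]. Genes normally kept silent in beta cells were higher in 9 of 10 cases (median 1.38, percentile 97.2 of matched lists), such as Cd302 at 7.05 [4.08 to 13.1] and Igfbp4 at 4.31 [3.19 to 5.92]. The exception was Ldha, which makes lactate from pyruvate, at 0.180 [0.138 to 0.232].

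**Figure D1:**
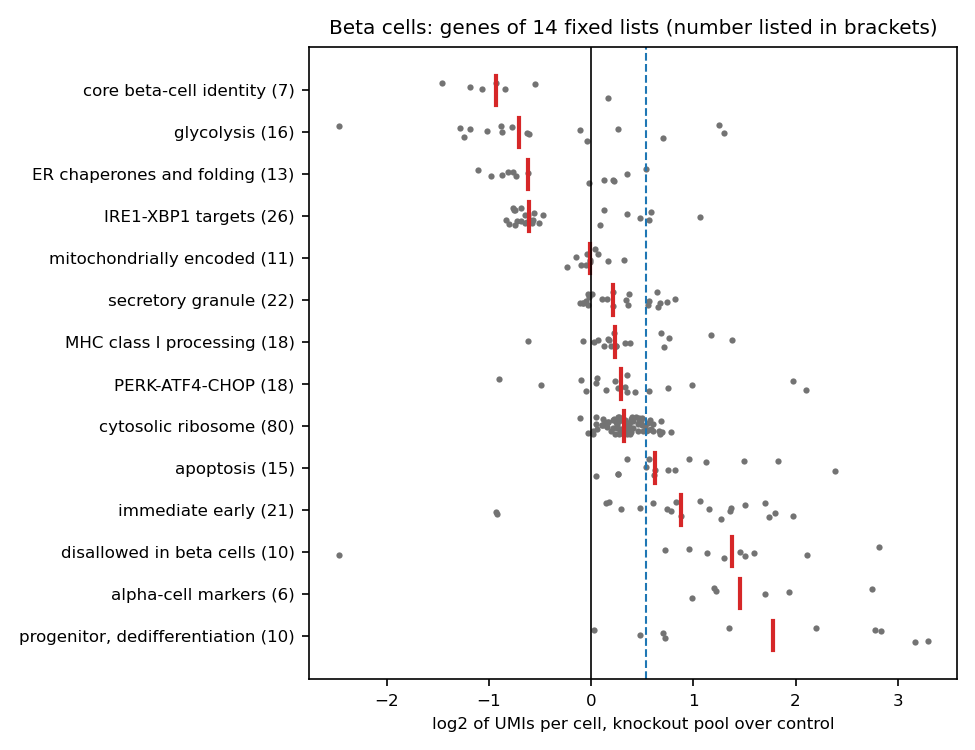
Each dot is the log2 ratio of UMIs per cell, pooled knockout over control, of 1 gene in beta cells, grouped by 14 gene lists fixed beforehand with the number of measured genes in brackets. Red bars are list medians, the solid line marks equal UMIs per cell and the dashed line the median of all listed genes (0.54). Core identity genes (median -0.93) and IRE1-XBP1 targets (-0.61) lie to the left and progenitor genes (1.78) to the right, while lists between the lines, such as the cytosolic ribosome, are higher as UMIs per cell and lower relative to all genes.

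Genes of the ER secretory machinery were lower. Of 26 measured IRE1-XBP1 target genes, 19 were lower and 23 lay below the median of all genes, with a median log2 fold of -0.61 (-1.15 relative to all genes), below all 10000 matched lists. Sec61g, a subunit of the ER translocon, went from 25.7 to 14.4 UMIs per cell, a ratio of 0.560 [0.547 to 0.573], and the signal peptidase subunit gene Spcs3 was at 0.574 [0.535 to 0.615]. Derl3, which acts in ER-associated degradation, went the other way at 2.09 [1.65 to 2.68]. ER chaperones and folding enzymes were lower in 8 of 13 cases (median -0.61), led by Fkbp2 at 0.463 [0.443 to 0.484] and Ero1l at 0.506 [0.470 to 0.544]. The chaperone genes Hspa5 (1.16 [1.13 to 1.20]) and Hsp90b1 (1.45 [1.40 to 1.5]) were higher as UMIs per cell, and both lay below 0 on the log2 scale after centring on the median of all genes.

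Other gene groups of the stress response did not move as one. The PERK-ATF4-CHOP list had 14 higher and 4 lower genes at a median of 0.30 (percentile 49.2, or 0.33 among lists not matched on expression). Its extremes were Gdf15 at 4.29 [3.45 to 5.38] and Atf3 at 3.94 [3.44 to 4.53], against Psat1 of serine synthesis at 0.534 [0.464 to 0.614]. Ddit3, which encodes CHOP, was at 1.26 [1.19 to 1.33] and Atf4 at 1.03 [0.992 to 1.07], and both lay below the median of all genes. Of the substrates of IRE1-dependent mRNA decay, 4 of 5 were higher (median 1.06, percentile 96.4), with Galnt10 at 2.35 [1.81 to 3.08] and Pmp22 at 0.310 [0.172 to 0.534]. Txnip, which binds thioredoxin, was at 3.55 [3.13 to 4.04].

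Glycolysis genes were lower in 12 of 16 cases (median -0.70, below all 10000 matched lists), among them Ldha and Slc2a1, a glucose transporter gene, at 0.410 [0.358 to 0.469]. Bnip3 (0.359 [0.327 to 0.393]) and Hilpda (0.364 [0.307 to 0.430]), both known to be induced by hypoxia, were among the 10 lowest, as were Ldha and Mafa. The rest of those 10 were Cartpt, a neuropeptide gene (0.148 [0.121 to 0.179]), Traf3ip2 (0.350), Isg15 (0.354), Fkbp11 (0.355), Adam32 (0.364) and Dll1 (0.364). The metallothionein genes Mt1 and Mt2 went from 244 to 93.9 and from 169 to 67.0 UMIs per cell. Other oxidative stress genes were mostly higher, 23 of 25 in all at a median of 0.40 (-0.14 relative to all genes), led by Gpx3 at 6.52 [6.20 to 6.85].

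For antigen presentation, B2m, the constant chain of MHC class I, went from 9.91 to 6.47 UMIs per cell, a ratio of 0.653 [0.630 to 0.676]. Of the 18 measured genes of MHC class I processing, 16 were higher, with H2-T23 at 2.60 [2.26 to 2.99] and H2-Q7 at 2.26 [1.97 to 2.59] (median 0.23, percentile 7.31, and -0.31 relative to all genes); H2 genes are close copies whose reads may be split by the counting. The interferon response list was higher in 11 of 14 cases (median 0.29, -0.25 relative to all genes), but Isg15 (0.354 [0.320 to 0.391]) and Irf7 (0.551 [0.498 to 0.61]) were lower and Irf1 was at 2.36 [2.13 to 2.61].

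Transcripts of other cell types were mostly higher in the knockout beta cells, as were 95.0% of all listed genes, and 4 of 8 such lists exceeded the central 95% of matched lists. Ppy, the pancreatic polypeptide gene, went from 8.88 to 65.3 UMIs per cell, a ratio of 7.36 [7.18 to 7.54]. Pyy went from 12.8 to 41.6, Gcg, the glucagon gene, from 43.6 to 100.4 and Sst, the somatostatin gene, from 36.7 to 59.1 UMIs per cell. All 6 measured alpha-cell markers (median 1.46, above all 10000 matched lists), 4 of 4 delta-cell markers (0.95, percentile 92.2) and 3 of 3 PP and epsilon-cell markers (1.70, percentile 98.9) were higher; Pyy counts in the first and the last. So were 4 of 4 acinar genes (median 2.10, percentile 99.0), such as Reg3b, at least 31.5-fold higher against a floor of 3 UMIs over the control cells. Duct genes were higher in 8 of 8 cases (0.92, above all 10000 matched lists; Muc1 at 4.16 [3.30 to 5.29]) and mesenchymal genes in 6 of 6 (1.92, percentile 85.0; Col1a1 at least 12.5-fold higher against the same floor). Endothelial genes were higher in 2 of 3 cases (1.01, percentile 77.4; Pecam1 at 2.06 [1.68 to 2.52]) and immune-cell genes in 3 of 4 (1.22, percentile 89.7), with Cd68 of macrophages lower at 0.141 [0.102 to 0.192]. Red-cell RNA led the whole table: Hba-a1 had 0.0229 UMIs per control cell and 12.7 per knockout cell, Hbb-bs 0.0386 and 8.0, and Hbb-bt 0.00241 and 1.93, globin genes whose near-identical copies share reads. The other genes among the 10 highest were Cck (14.9 [9.77 to 23.8]), Pappa2 (12.7 [9.88 to 16.6]), Serpinb1a (9.88 [7.26 to 13.7]) and Phlda3 (6.53 [5.39 to 7.98]), next to Ppy, Cd81 and Gpx3.

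Immediate early genes, which also respond to tissue dissociation, were higher in 19 of 21 cases with a median of 0.88 that exceeded all 10000 matched lists. Zfp36 was at 3.47 [3.14 to 3.85], and the heat shock gene Hspa1a went the other way at 0.529 [0.476 to 0.588]. All 15 measured apoptosis genes were higher as UMIs per cell, 10 of them above the median of all genes (median 0.63, percentile 94.7), up to Tnfrsf10b at 5.21 [2.41 to 12.9]. Oxidative phosphorylation genes (48 of 77 higher, median 0.07) lay below all 10000 matched lists, and the cytosolic ribosome (78 of 80, 0.32) at percentile 99.1, though below all lists that were not matched on expression. Secretory granule genes (15 of 22, 0.21, Chgb at 1.67 [1.64 to 1.71]), proliferation (4 of 5, 0.40) and the proteasome (31 of 34, 0.28) were at percentiles 14.6, 49.2 and 18.6. The medians of all 5 lists lay below that of all genes. Mitochondrially encoded genes were at a median of -0.01 (percentile 0.99), with 4 of 11 higher, and at 0.33 after scaling to the listed total. Of the ER stress sensors only Ern1 was among the listed genes. Pdx1, Nkx6-1, G6pc2, Neurog3 and H2-K1 were not analysed here.

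In alpha cells, the listed glycolysis and ER secretory genes were lower in both knockout mice, while the listed ribosomal and mitochondrial genes were higher in their mean. These genes had been listed for differing in the same cells, so their shared direction does not describe the members that were not listed. Of the 186 genes, 80 were higher and 106 lower in the mean of the knockout mice (median log2 fold -0.29), and 20 higher and 56 lower by the size rule (47 and 26 after centring on the median, 35 and 35 after scaling to the listed total). For 164 genes, 69 higher and 95 lower, both knockout mice lay on the same side of the control, 88.2% against 66.7% for 3 mice that do not differ, although the genes had been chosen on the same cells. Mif, a cytokine gene, went from 8.94 to 3.77 ± 0.93 UMIs per cell (SD, n = 2), Tpi1 from 4.38 to 1.91 ± 0.463 and Gapdh from 14.1 to 7.86 ± 0.286, the latter pair being glycolytic. With the mouse as the unit, edgeR's quasi-likelihood test on recovered UMIs, which assumes that the single control varies like the knockouts, called 0 higher and 4 lower genes after Benjamini-Hochberg adjustment, and 5 and 47 at an unadjusted p under 0.05. With the listed UMI total in place of the cell number as offset it called 3 and 6. The 4 genes were S100a9, Mif, Aldoa and Gapdh, each at an adjusted p of 0.0392.

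All 10 measured glycolysis genes were lower in both knockout mice (median log2 fold -1.06), among them Ldha (0.528 to 0.109 and 0.0339 in the knockout mice), Eno1 (2.08 to 0.879 ± 0.060) and Aldoa (8.14 to 4.43, with both mice alike). The 8 measured IRE1-XBP1 targets were also lower in both mice (median -0.59), with the translocon-associated Ssr2 at 4.57 ± 0.109 against 7.39 and Spcs2 at 2.21 ± 0.141 against 3.52 UMIs per cell. Pdia6 was the 1 ER chaperone measured, at 2.40 ± 0.045 against 3.79. Of the beta-cell genes, Iapp was at 62.1 ± 10.6 against 126, Ins2 at 156 ± 6.44 against 214 and Ins1 at 59.6 ± 33.3 against 93.6 UMIs per cell. Control alpha cells held 1.60% and 1.36% of the beta-cell levels of Ins2 and Ins1, shares that free RNA from beta cells can supply, so the insulin values are not taken as expression by alpha cells; for Iapp the share was 7.06%. Ins1 differed more between the knockout mice (36.0 and 83.1) than their mean differed from the control. Ppy was lower at 332 ± 13.2 against 427, opposite to beta cells. Sst, at 12.1 and 42.0 in the knockout mice against 36.8, was on both sides of the control. The 5 secretory granule genes were lower in the mean, such as Resp18 (44.2 ± 2.66 against 63.6) and Vgf (3.11 ± 0.586 against 5.65), 4 of them in both mice.

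Among the other lowest genes of alpha cells were Rbp4 (8.67 ± 1.75 against 15.7), Id3 (1.34 and 2.69 in the knockout mice against 3.61), Ctsl (11.9 ± 0.251 against 20.1) and Igfbp7 (5.81 ± 0.645 against 9.74). Less expressed and also lower were Cebpb of the PERK-ATF4-CHOP list (1.54 ± 0.146 against 3.11) and Gstp1 of the oxidative stress list (0.622 ± 0.0707 against 1.46). The highest, under the limit on expression above, were Defb1 (8.59 ± 4.99 against 4.30, with 5.06 and 12.1 in the knockout mice), Serpina3n (4.45 ± 0.437 against 2.72) and mt-Nd3 (8.15 ± 0.745 against 5.39). Ang and Rnase4, which share a locus, and the immediate early gene Egr1, Wdr89, Rps27rt, Rps27 and Ptms followed at ratios of 1.39, 1.38, 1.37, 1.33, 1.32, 1.27 and 1.25; Ang was lower than the control in the mouse of the first column. All 19 cytosolic ribosome genes (median 0.17) and all 11 mitochondrially encoded genes (0.19) were higher in the mean, 18 and 8 of them in both mice. Of the remaining lists with at least 3 measured genes, oxidative phosphorylation (4 of 4 lower, -0.46) and oxidative stress (3 of 3 lower, -0.44, or -1.36 without the mouse of the second column) pointed down and the immediate early list had 1 higher and 2 lower genes. The autoantigen median (-0.56, 4 of 4 lower) lies between Ins1 and Ins2 and is not taken as expression by alpha cells either. The interferon gene Rsad2 was higher only in the mouse of the second column (0.0691 and 0.638 against 0.183).

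Delta cells of the knockout mice had more immediate early transcripts and less Iapp, and more glucagon transcripts of unknown origin. Gcg went from 10.0 to 111 ± 67.6 UMIs per cell (SD, n = 2; 159 and 63.5 in the knockout mice), a ratio of 11.1. Free glucagon RNA and mixed cells were not excluded, since beta cells gained 56.9 Gcg UMIs per cell against 149.1 and 53.5 in delta cells. Fos was at 6.38 ± 0.713 against 2.96 and Btg2 at 7.87 ± 1.27 against 3.32, and all 9 measured immediate early genes were higher in both mice (median log2 fold 0.79). Iapp was at 748 ± 70.4 against 1825, and edgeR's test, given below, called it only with the listed total as offset and not with the cell number. Iapp itself made up 49.7% of that total in the control and 26.0% and 26.4% in the knockout mice. The call with that offset is therefore not separate evidence of lower Iapp. Of the 231 genes, 188 were higher and 43 lower in the mean (median 0.42), and 95 higher and 37 lower by the size rule (45 and 42 after centring on the median). After scaling to the listed total without Ins1, Ins2 and Iapp, 65.4% were higher in place of 81.4%. Both knockout mice lay on the same side of the control for 165 higher and 41 lower genes, 89.2% of those listed. With the mouse as the unit, edgeR's test called 28 higher and 22 lower genes, and 82 and 8 with the listed total as offset.

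Glycolysis genes were lower in 5 of 5 cases (median -0.98), with Ldha at 0.493 ± 0.153 against 2.05, Eno1 at 1.17 ± 0.299 against 2.69, Tpi1 at 2.07 ± 0.372 against 4.09 and Pgam1 at 2.05 ± 0.177 against 3.85. With the listed total as offset, edgeR's log2 folds of these genes were -1.69, -0.84, -0.62 and -0.55, and Eno1, Tpi1 and Pgam1 were no longer called. Without Iapp, however, the listed total per delta cell was 1.23 and 1.05 times the control in the knockout mice. That offset therefore weakened the folds through the fall of Iapp. IRE1-XBP1 targets were lower in 7 of 7 cases (median -0.70), including Manf (8.64 ± 1.46 against 13.4) and Edem2 (1.46 ± 0.348 against 2.59), in each case in both mice. With the listed total as offset, edgeR's log2 folds were -0.28 for Manf and -0.47 for Edem2. Manf was then no longer called, and Edem2 was called with neither offset. Other genes among the 10 lowest were S100a6 (1.70 ± 0.714 against 4.93), Tspan8 (2.24 ± 0.41 against 5.29), Mt1 (16.0 ± 4.77 against 37.7), Fkbp11 (2.38 and 1.10 in the knockout mice against 4.08), the tight junction gene Cldn7 (7.60 ± 0.294 against 15.6), Rbp4 (76.6 ± 10.7 against 137) and Epcam (10.4 ± 1.07 against 18.4). Slc7a3, an amino acid transporter gene, had 17 UMIs in the control and 2 over both knockout mice. Markers of alpha cells split, with Ttr higher (3.47 ± 1.26 against 1.01) and Gc lower (1.39 ± 0.024 against 3.12).

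Higher in both knockout mice were also Errfi1 (3.62 ± 1.19 against 1.72), Serping1 (4.06 ± 0.326 against 2.05), Egr1 (4.38 ± 0.352 against 2.53), Sod2 (5.80 ± 0.262 against 3.40), Junb (11.5 ± 0.534 against 7.46) and Socs3, an inhibitor of cytokine signalling (1.64 ± 0.233 against 0.822). Mitochondrially encoded genes were higher in 10 of 10 cases in both mice (median 0.61), such as mt-Nd1 (28.8 ± 8.41 against 17.9) and mt-Nd4 (16.5 ± 5.17 against 10.7). The 38 ribosomal (median 0.10) and 5 oxidative phosphorylation genes (0.15) were higher in the mean, 27 and 5 of them in both mice; both medians lay below 0 once scaled to the listed total without Iapp or centred on the median of all genes. The beta-cell identity list had Glul (2.24 ± 0.499 against 0.98) and Rgs4 (3.29 ± 0.246 against 1.90) higher and Iapp lower. The complement gene C1qa of macrophages was at 0.833 and 0.346 in the knockout mice against 1.04.

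**Figure D2:**
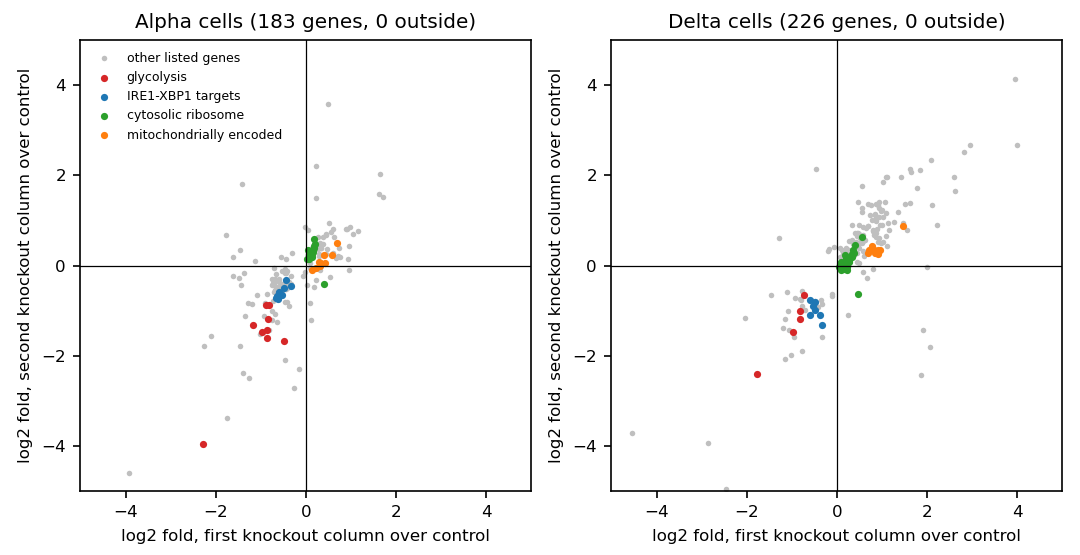
Each dot is 1 gene with UMIs in all 3 columns, 183 of 186 in alpha and 226 of 231 in delta cells. The axes give the log2 ratio of UMIs per cell over the control for the mouse of the first and of the second knockout column. Glycolysis genes (red) and IRE1-XBP1 targets (blue) lie below 0 in both mice in both cell types; ribosomal (green) and mitochondrial genes (orange) lie mostly above 0, and the median of delta-cell ribosomal genes goes below 0 when centred or scaled to the listed total without Iapp.

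Genes listed in more than 1 cell type mostly moved the same way. Alpha and delta cells shared 68 genes, of which 47 were higher and 18 lower in both and 3 opposite, 95.6% in the same direction. Because the cells came from the same 3 mice, agreement above chance arises with no effect of genotype. A simulation of unchanged mice, with the covariance between cell types estimated from the difference between the knockout mice, gave 72.5% on average and 82.4% at the upper end of the central 95% of simulations. The covariance of log2 folds across these genes was 0.440, against a simulated 0.058, and their correlation 0.865 against 0.648. The genes had been listed for differing in both cell types, which favours large folds and which the simulation leaves out, so the gaps to the simulated values do not measure a shared effect. Independent lists of these lengths would share 0.977 higher and 0.296 lower genes among 15393 tested, a number recovered from the p and q values of the authors' deposited table. Part of the excess may come from the shared control, and the genes are not independent replicates. Centred on each table's median, 66.2% had the same direction.

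Beta and delta cells shared 207 genes, 161 higher and 18 lower in both and 28 opposite (86.5% the same; independent lists would share 95.0 and 1.15). Beta and alpha cells shared 162 genes, 66 higher and 38 lower in both and 58 opposite (64.2% the same; independent lists would share 38.5 and 2.71). Independent lists leave out the shared mice, and unchanged mice were not simulated for these pairs, because the beta-cell column pools the knockout mice. How much of their agreement the shared mice account for is therefore not known. In addition, 95.0% of beta-cell and 81.4% of delta-cell genes were higher, so many shared genes would agree through these shares alone. The opposite count that independent lists would give was not computed. Centred on the medians, 71.0% had the same direction between beta and delta and 56.2% between beta and alpha cells. Among genes with a fold of at least 1.5 in both tables, 19 of 19 moved alike between alpha and delta, 65 of 71 between beta and delta and 31 of 41 between beta and alpha cells.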

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

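The tests in this part were chosen only after the results were seen. Genes below differed between cell types in direction, with every column of one cell type moving one way and every column of the other the opposite way; the beta-cell value is the authors' pool of both knockout mice, and the difference between cell types was not tested. Against alpha cells, in which both knockout mice lay below the control, the beta-cell log2 fold was larger by 3.24 for Ppy, 2.42 for Gstp1, 1.75 for Rbp4, 1.45 for Ctsl, 1.44 for Cebpb, 1.23 for Igfbp7, 1.23 for Vgf, 1.1 for Id3 and 0.77 for Epcam. For Serpina3n, higher in alpha cells, the difference of beta minus alpha cells was -0.77. Against delta cells, in which both knockout mice lay below the control, the beta-cell log2 fold was larger by 3.29 for S100a6, 2.16 for Gc, 1.74 for Rbp4, 1.72 for Tspan8 and 1.12 for Epcam. For Serpina3n, mt-Nd1 and mt-Nd4, higher in delta cells, the difference of beta minus delta cells was -2.89, -0.92 and -0.73. Because the median of all listed genes was 0.54 in beta, -0.29 in alpha and 0.42 in delta cells, part of each difference against alpha cells, apart from that of Serpina3n, which points the other way, belongs to the whole table. Centred on these medians, 7 of the 18 opposite directions ended, as Cebpb, Id3, Igfbp7, Vgf and Epcam against alpha cells and Epcam and Tspan8 against delta cells were lower in both. After scaling to the listed total, Serpina3n, mt-Nd1 and mt-Nd4 lay above 0 in beta cells too.

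Of the listed beta-cell genes, 95.0% had more UMIs per cell in the knockout. The authors' scaling to total counts was set against this first: among the 482 genes with at least 3 UMIs per control cell, the stretch of log2 folds 0.2 wide with the fewest genes was centred on -0.35 and held 0 genes, against 119 in the stretch centred on 0. The log2 ratio of listed totals was -0.35 too, which is consistent with a test that compared shares of a total mostly made of insulin, so that 95 abundant genes between that ratio and 0 may be listed for a higher share at fewer UMIs per cell. How much of the 95.0% comes from which genes were listed stays open, as unlisted genes were not analysed here. A single factor for every gene other than insulin is argued against as the whole cause. Ribosomal genes exceeded mitochondrially encoded ones by 0.34 in median log2 fold, with a standard error of 0.050 over genes. That error treats the genes as independent and does not cover the spread between mice. An effect of the deletion and a difference of the single control mouse or its library, unrelated to the deletion, cannot be told apart with 1 control mouse.

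Lower beta-cell genes came together with higher hormone transcripts of other islet cells in the knockout beta cells. If alpha or delta cells counted as beta cells were the whole cause, the core identity median would need 47.5% of such cells, and they would bring their own transcripts. The knockout beta cells held 65.3 Ppy UMIs per cell against at least 323 in alpha cells of either knockout mouse, and 0.216 Tspan8 UMIs against at least 1.95 in delta cells. These second strictest genes of the 2 types allow at most 20.3% and 11.1%, or 31.3% in all. Alpha and delta cells with the mean levels of their type are therefore argued against as the whole cause. The limit rests on few genes, as 4 of 114 in alpha and 4 of 158 in delta cells allow less than the share needed. Ppy is also a marker of PP cells, so its limit need not hold for alpha cells that lack it. The next strictest genes allow 31.4% (Igfbp7 in alpha cells) and 27.0% (Epcam in delta cells), which together would not suffice. Cells of other types, for which no table was analysed here, stay open as a cause of dilution. A lower total per cell is argued against as well, as the core identity median was -0.58 after scaling to the listed total. For the hormones, free glucagon RNA cannot be told apart from expression or mixed cells, because the gain of 56.9 Gcg UMIs per beta cell lies between the gains per delta cell in the knockout mice, 149.1 and 53.5. An effect of the deletion on beta cells stays open and untested, as does a difference of the single control mouse or its library, unrelated to the deletion, which cannot be excluded with 1 control mouse.

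The listed glycolysis and XBP1 target genes were lower in their median in all 3 cell types, although the knockout is labelled as one of beta cells. Free beta-cell RNA carrying the change into other cells is argued against: over 25 pairs of gene and cell type the control level outside beta cells was at least 56.5% of that in beta cells, while Ins2 in control alpha cells was at 1.60% of its beta-cell level. The list medians argue against fewer counts per knockout cell as the whole cause. Without Ins1, Ins2 and Iapp, the listed total per knockout cell was 1.20 times that of the control in beta cells. In delta cells it was 1.23 and 1.05 times in the knockout mice. The lower listed totals of beta and delta cells thus lay in these hormone genes. In alpha cells it was 0.934 and 0.937 times, so fewer counts can account for part there. Of both lists in the 3 cell types, the median nearest to 0 after scaling to the listed total was that of XBP1 targets in beta cells. It went from -0.61 to -0.26, with a standard error of 0.106 over genes, which does not cover the spread between mice. With the listed total as offset, edgeR's test no longer called the XBP1 target Manf in delta cells, where that total includes the fall of Iapp. The test called Edem2 in delta cells and Ssr2 and Spcs2 in alpha cells with neither offset. A difference of the single control mouse or its library, unrelated to the deletion, such as the state of its islets after culture, cannot be told apart from an effect of the deletion, on beta cells or through them on their neighbours, with 1 control mouse.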

How the results depend on the processing

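The scalings to listed totals, the fold in each knockout mouse and edgeR's test were chosen after seeing the data. Counts by size depended on every threshold, as fewer genes pass a stricter one. At a fold of 2 there were 1626 higher and 99 lower genes in beta, 5 and 22 in alpha and 46 and 15 in delta cells. Among the better expressed genes of each table alone (fewer genes by construction) there were 1043 and 112 in beta, 3 and 20 in alpha and 20 and 21 in delta cells. With a pseudocount, which shrinks the folds of rare genes, 2171 genes were higher in beta, 10 in alpha and 60 in delta cells. Centred on the median, there were 1314 higher and 343 lower genes in beta, 47 and 26 in alpha and 45 higher in delta cells. Scaled to the listed total, there were 6816 and 112 in beta, 35 and 35 in alpha and 146 and 17 in delta cells, and without Ins1, Ins2 and Iapp in that total 2104 were higher in beta cells. A fold of at least 1.5 in each knockout mouse was reached by 11 higher genes in alpha and 63 in delta cells. edgeR called 0 higher and 4 lower genes in alpha and 28 and 22 in delta cells with the cell number as offset, and 3 and 6 in alpha and 8 lower in delta cells with the listed total. Requiring the authors' adjusted p to be under 0.05 removed no gene, so it tested nothing. Other counts stayed within 1.5 times those reported, and so did the 8 counts that leave out either knockout mouse in alpha or delta cells. Beta cells allowed no such step, as their knockout column is pooled. Rescaling without the 10 most abundant genes was not run, since the means do not add up to a fixed total. No paired analysis was possible because the groups share only 1 replicate number, the control being 1 mouse.

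Some directions turned with the scaling, by its own construction. Centred on the median of all genes, these lists in beta cells had medians below 0: beta-cell identity (-0.45), PERK-ATF4-CHOP (-0.24), MHC class I processing (-0.31), interferon response (-0.25), secretory granule (-0.33), proliferation (-0.14), oxidative stress (-0.14), cytosolic ribosome (-0.22), oxidative phosphorylation (-0.47) and proteasome (-0.26). So did the genes Neurod1 (-0.38), Hsp90b1 (-0.0054), Hspa5 (-0.33), Ddit3 (-0.21), Atf4 (-0.50), Cebpb (-0.11), Id3 (-0.28), Igfbp7 (-0.050), Vgf (-0.18), Epcam (-0.24) and Tspan8 (-0.056). In delta cells the same held for the ribosome (-0.32), oxidative phosphorylation (-0.27) and Lcn2 (-0.30). Scaled to the listed total without Ins1, Ins2 and Iapp, the turned values in beta cells were identity (-0.18), MHC class I processing (-0.036), secretory granule (-0.055), oxidative phosphorylation (-0.19), Neurod1 (-0.11), Hspa5 (-0.053), Atf4 (-0.22) and Id3 (-0.0079), and in delta cells the ribosome (-0.088), oxidative phosphorylation (-0.039) and Lcn2 (-0.040). Scaled to the listed total, the medians of autoantigens (0.021) and mitochondrially encoded genes (0.33) in beta cells turned above 0, as did Serpina3n (0.29), mt-Nd1 (0.11) and mt-Nd4 (0.25). In alpha cells, leaving out either knockout mouse gave log2 folds of -1.61 and 0.19 for Sst, -0.020 and 0.85 for Ang and -1.41 and 1.80 for Rsad2, and in delta cells -0.18 and 0.37 for Lcn2. No other list, and no other gene among those run under these settings, changed direction. Centring nevertheless moved 29 lists by more than their standard error over genes, and 129 genes by more than the counting error of their ratio. Leaving out the first or second knockout mouse moved 39 and 32 genes by more than that counting error. Random lists without matching moved the percentile of 12 of 29 beta-cell lists by 5 points or more, and took some from one end to the other: the cytosolic ribosome from 99.1 to 0.0 and oxidative stress from 86.9 to 5.52, with PERK-ATF4-CHOP from 49.2 to 0.33.

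The share of shared genes with the same direction rose among those with a fold of at least 1.5 in both tables, to 75.6% (beta and alpha), 91.5% (beta and delta) and 100% (alpha and delta), and was lower after centring, at 56.2%, 71.0% and 66.2%; the cause was not tested. Depth limits the rare genes, whose ratios rest on few UMIs, and the alpha and delta tables, with 78 to 304 cells per mouse.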

Other observations

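Apart from Phlda3, one of the 10 highest, the genes in this and the following paragraph were chosen after their values were seen. No gene list was fixed or tested for them, so they describe single genes and no group. In knockout beta cells, where 95.0% of listed genes were higher at a median ratio of 1.45, Phlda3 was at a ratio of 6.53 [5.39 to 7.98], Eda2r at 6.89 [3.40 to 15.8], Trp53inp1 at 3.23 [2.69 to 3.90], Ccng1 at 2.97 [2.73 to 3.24], Cdkn1a at 2.17 [2.06 to 2.29] and Mdm2 at 1.66 [1.47 to 1.86], each in brackets with the interval that covers counting error only. Lower genes were picked in the same way: Ak4 was at 0.142 [0.0918 to 0.211], Slc16a3, a lactate transporter gene, at 0.177 [0.103 to 0.290] and Pdk1 at 0.470 [0.363 to 0.605], while Mif went from 18.1 to 8.06 UMIs per cell.

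In delta cells, where 81.4% of listed genes were higher, Lrg1 was at 2.46 ± 0.239 UMIs per cell (SD, n = 2) against 0.149 in the control, Hamp at 2.86 ± 0.421 against 0.446 and Serpina3n at 1.68 ± 0.242 against 0.238. The chemokine gene Ccl2 was at 1.70 and 0.679 in the knockout mice against 0.366, and Fgl2 at 0.802 ± 0.171 against 0.218. Lcn2, in contrast, was on both sides of the control, at 5.27 and 7.71 against 5.97.

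Hemoglobin in knockout beta cells amounted to 18450 UMIs over 815 cells for Hba-a1, Hbb-bs and Hbb-bt, a total that a small number of droplets can hold; values per cell were not analysed here. Insulin UMIs in alpha cells differed between the knockout mice in composition. There were 43.7 Ins1 per 100 Ins2 UMIs in alpha cells of the control, 22.5 in the mouse of the first and 54.9 in that of the second knockout column, against 51.6 in beta cells of the control and 35.9 in the pooled knockout beta cells.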
